A study of Homo sapiens with 6 samples.

How the data were processed

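The series profiled poly(A)-selected RNA from T-24, an established human urinary bladder cancer cell line, after 48 h with CCT068127 at 1 µM or with its vehicle, DMSO. Each arm had 3 samples, described per the labels as independent biological replicates, and the groups and replicate numbers were taken from the sample titles. Libraries were made after magnetic poly(A) isolation with a NEB Ultra II kit and sequenced on a NovaSeq, per the labels' protocols. Strandedness is not given in the sources used here, so reads of a gene and of an overlapping antisense gene could not be separated.

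The authors deposited estimated counts per gene symbol, rounded to whole numbers, and TPM values from the same quantification. RSEM, Bowtie and the build hg38 are named in the submitters' processing notes, with no versions, and the annotation is not given in the sources used here. Both deposited tables held 38557 gene symbols. Between 27 and 203 genes per library had a deposited count of 0 beside a TPM above 0, a trace of the rounding of expected counts. Every column matched a sample by its title.

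The total counts were 371044040 and 411097626 in DMSO replicates 1 and 2 and 5955296 in DMSO replicate 3. They were 5557546, 1966742 and 4657316 in CCT068127 replicates 1 to 3. A gene with 0 counts was limited, at 3 counts of the total, to 0.00808, 0.0073 and 0.504 CPM in the DMSO libraries and to 0.54, 1.52 and 0.644 CPM in the CCT068127 libraries. Intervals and floors cover counting error only, since no molecular identifiers were used. The precision of most values was set by the 4 shallow libraries.

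The counts were analysed in R 4.3.3 with edgeR 4.0.16. Low-count genes were removed with filterByExpr (a minimum count of 10, equal to 1.74 CPM at the median library, in at least 3 libraries), which left 13597 genes. Libraries were scaled by TMM, a quasi-likelihood model with robust dispersion and treatment as its term was fitted, and p-values were adjusted by the Benjamini-Hochberg method, with calls at an adjusted p under 0.05. The p-values of single genes in the text are from this two-sided test unless another is named. Standard errors (SE) of log2 fold changes were approximated from the F statistic. CPM values are given per group as mean ± SD over 3 libraries and were computed with the TMM-scaled totals. The words rose and fell are used for genes past the threshold.

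The design, 28 gene lists, the rule for named genes and 39 pairs of a result and an alternative were fixed before the data were examined. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 28 lists. Camera with an estimated correlation and fry were the alternatives. The text names 9 genes chosen in advance (CDK2, CDK9, CCNE1, CCNE2, CCNA2, CCNT1, HEXIM1, MYC, MCL1), the 8 highest and 8 lowest fold changes among called genes with a mean of at least 5 CPM and no overlap between the groups, and from each list up to 3 called members in its more common direction and 1 in the other, by smallest adjusted p. The mitochondrially encoded genes were matched under the symbols without a prefix used in the deposited tables. Some genes that the rule selects are not reported here by name, though they remain in the counts of their lists. Of 5 further lists, 1 (RNAs without a poly(A) tail) was written before its values were seen and 4 (metallothioneins, cytosolic aminoacyl-tRNA synthetases, NRF2 targets, proteasome subunits) after the genes with the largest changes had been seen. They were adjusted over those 5 lists.

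Alternatives fixed in advance were DESeq2 size factors and upper-quartile scaling in edgeR, no low-count filter, the replicate number as a block and leaving out each library. DESeq2 1.42.0, limma-voom and limma-trend on TPM values were also fixed in advance. Limma-trend was run on log2(TPM + 1) with and without a filter of 1 TPM in 3 libraries, and on log2(TPM + 0.1) with that filter. Alternatives added after seeing the depths were random thinning of DMSO replicates 1 and 2 to the total of DMSO replicate 3 with 1 draw, DMSO replicate 3 as the sole control, and scaling by library totals. With DMSO replicate 3 as the sole control the DMSO group has no spread of its own, so only effect sizes are given for that fit. Fold changes from TPM are on the log2(TPM + pseudocount) scale, which understates the change of low genes. No spike-in was named in the labels, so changes are relative to the other genes of a library.

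Within DMSO, the replicate pair closest in counts was 2 and 3, with a chi-square per degree of freedom of 1.89 after DMSO replicates 1 and 2 had been thinned to the total of DMSO replicate 3. The other pairs within a group had values from 4.16 to 8.36. No pair agreed within counting noise, so none was treated as 1 library deposited again, though this does not show that the replicates are independent. Each library counted as 1 replicate, as the labels describe them.

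Gene positions, genomic lengths, transcript lengths and GC content were taken from GENCODE release 29 on GRCh38, the assembly called hg38, by symbol. A length was found for 12957 of the 13597 tested genes (95.3%). Neighbouring genes were compared with Python 3.11.15 and SciPy 1.17.1.

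The procedures were tested on simulated counts with known changes, drawn with the real means and library sizes. For CCT068127 against DMSO over 13407 tested genes, edgeR recovered 80.2% of genes made to change 2-fold and 99% of those made to change 4-fold, with 6 calls among unchanged genes. With no change simulated it made 0 calls, 5.04% of genes had an unadjusted p under 0.05, and DESeq2 and limma-voom also made 0 calls. The list test called the simulated shifted list and 0 of 20 unchanged lists over 13381 genes. The simulated genes were drawn independently, and far fewer were made to change than were called in the data. In the data the estimated correlation within the fixed lists ran from -0.155 to 0.988. The simulation therefore does not test the preset correlation on lists whose genes vary together.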

Results

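Gene expression was measured by poly(A) RNA-seq in T-24 cells, an epithelial line from a human urinary bladder cancer, treated for 48 h with 1 µM CCT068127 (3 libraries) or with DMSO (3 libraries). CCT068127 is a compound known as an inhibitor of the cyclin-dependent kinases CDK2 and CDK9. The series comes from a study that compared pathway analysis methods in bladder cancer, and its single comparison asks which transcripts differed between treated and vehicle cells. Library totals were 371044040 and 411097626 counts in DMSO replicates 1 and 2, 5955296 in DMSO replicate 3, and 5557546, 1966742 and 4657316 in CCT068127 replicates 1 to 3.

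Relative to other transcripts, CCT068127-treated cells had higher levels of DNA replication, cholesterol synthesis, immediate early, chaperone and basal urothelial marker genes, and lower levels of integrated stress response genes, than DMSO-treated cells. These list results rest on a preset correlation between genes, and with an estimated correlation their adjusted p were 0.159 to 0.224 and 0 of the 28 lists passed. Of the 13597 genes tested, 8793 (64.7%) passed an adjusted p of 0.05, with 4333 higher and 4460 lower. At least 2-fold changes were seen in 3868, with 2108 higher and 1760 lower (edgeR, n = 3 per group). The groups did not overlap for 9430 genes (69.4%), against a chance share of 10%. With DMSO replicates 1 and 2 thinned to the total of DMSO replicate 3, and CCT068127 replicate 2 left at 1966742 counts, the component with the largest variance (83.7%) separated the groups, with scores from -72.3 to -64.3 in DMSO and from 66.8 to 72.5 in CCT068127. The next component (8.13%) set CCT068127 replicate 2 (-41.1) apart from CCT068127 replicates 1 (30.9) and 3 (11.7). The median log2 fold change over the tested genes was -0.05 with TMM and -0.36 with scaling by library totals, and this shift of the zero line moved the split of calls to 3006 higher and 6567 lower. On log2(TPM + 1) values the split was 2474 higher and 7472 lower. Small changes therefore have a direction relative to the scaling used.

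The kinases that the compound is known to inhibit moved apart. CDK2 (chromosome 12, 55966769 to 55972784, GRCh38), which drives S phase, rose from 30.6 ± 5.88 to 68.8 ± 2.37 CPM (SD, n = 3), a log2 fold change of 1.15 ± 0.14 (SE; edgeR adjusted p = 4.5e-05). CDK9 (chromosome 9, 127785679 to 127790787), the kinase of the elongation factor P-TEFb, fell from 80.7 ± 3.31 to 66.9 ± 3.76 CPM, a log2 fold change of -0.27 ± 0.10 (edgeR adjusted p = 0.0305). Its call was lost with DESeq2 size factors (adjusted p = 0.053), with the replicate number as a block (0.0611) and with the deep libraries thinned (0.0652). It was also lost without DMSO replicate 2 or CCT068127 replicate 3 (0.101 in each fit). With DMSO replicate 3 as the sole control the log2 fold change of CDK9 was -0.23. The CDK2 partners CCNE1 (1.73 ± 0.23) and CCNE2 (3.09 ± 0.23) rose. CCNA2 also rose, by 0.56 ± 0.20, but lost its call when any library other than DMSO replicate 1 was left out (adjusted p from 0.0677 to 0.232, with a log2 fold change of 0.36 without CCT068127 replicate 3). CCNT1, the cyclin of P-TEFb, rose by 0.62 ± 0.18, or by 0.35 without CCT068127 replicate 2, and its call was lost with scaling by library totals (adjusted p = 0.155). HEXIM1, the inhibitor that holds P-TEFb inactive, fell by 0.70 on the log2 scale. MYC rose by 0.68 ± 0.10, with no call on log2(TPM + 1) values (0.18, adjusted p = 0.121). MCL1, a short-lived survival transcript, stood at 336 ± 9.2 CPM in DMSO and 310 ± 28.1 CPM in CCT068127 and did not pass (log2 fold change -0.12 ± 0.10, adjusted p = 0.301). It stood at -0.08 without CCT068127 replicate 1 and at -0.19 without CCT068127 replicate 2, with no call in either fit. With scaling by library totals it passed as lower (-0.43, adjusted p = 0.0029). It also passed as lower without a low-count filter (-0.36, adjusted p = 0.033). On log2(TPM + 1) values it passed as lower with a filter (-0.61, adjusted p = 0.0012) and without one (adjusted p = 0.005). The same held on log2(TPM + 0.1) values (-0.61, adjusted p = 0.0015).

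**Figure D1:**
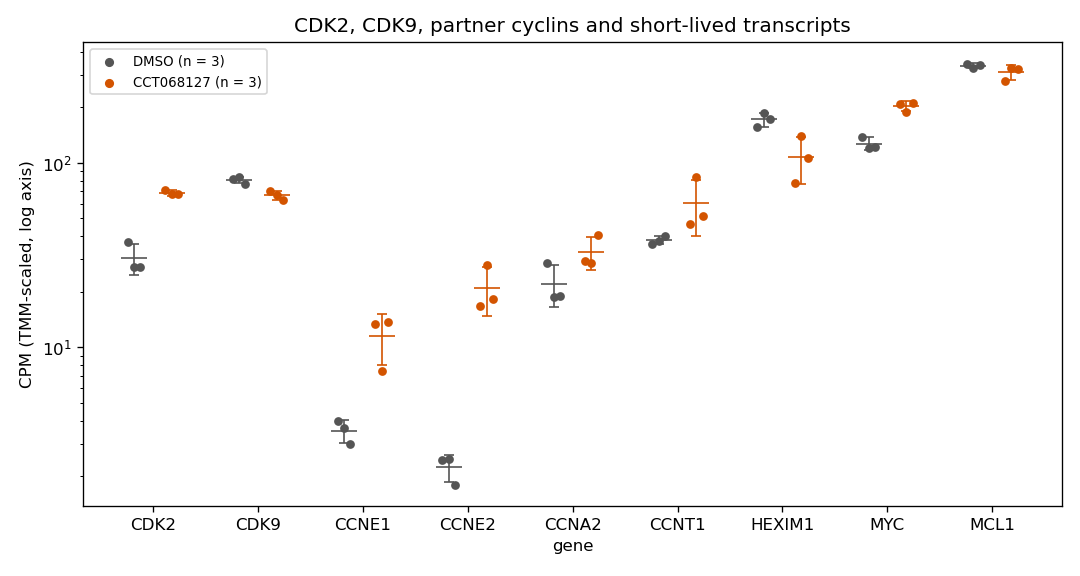
TMM-scaled CPM on a log axis for the 9 genes chosen in advance, per library, with DMSO in grey and CCT068127 in orange (points are libraries, n = 3 per group, bars are mean ± SD). CDK2 rose from a mean of 30.6 to 68.8 CPM, CCNE2 rose by 3.09 on the log2 scale, and the groups lie close together for CDK9 and MCL1.

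The list of 22 tested cyclin-dependent kinases and partner cyclins had 13 members that rose and 4 that fell. CCND3, a D-type cyclin, rose by 1.61 and CDK12, an elongation kinase, fell by 0.43 on the log2 scale. The list did not pass with camera (adjusted p = 0.118) but passed with fry as higher (adjusted p = 0.00194). Its median of 0.46 turned to -0.02 on log2(TPM + 1) values, with 6 members higher and 7 lower. Of 14 inhibitors of these kinases and related pocket proteins, 4 rose and 6 fell. CDKN1C, which encodes p57, rose 19.9-fold, from 13.9 ± 1.79 to 281 ± 43 CPM. CDKN1B, which encodes p27, fell by 1.76, CDKN2B, which encodes p15, by 1.42 and RBL2 by 0.61 on the log2 scale. That list did not pass (adjusted p = 0.755), and its median (-0.29) and mean (0.08) differed in sign. The median was -0.17 without DMSO replicate 1, -0.42 without CCT068127 replicate 2 and -0.13 with DMSO replicate 3 as the sole control.

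Replication genes rose together. All 32 tested members of the DNA replication and E2F target list rose, with a median log2 fold change of 2.08 (camera adjusted p = 1.22e-21; adjusted p = 0.159 with an estimated correlation). FEN1, the flap nuclease of Okazaki fragment maturation, rose from 29.4 ± 4.76 to 238 ± 13.5 CPM, and PCNA, the sliding clamp, from 44 ± 2.16 to 188 ± 5.48 CPM. Of 30 DNA repair and Fanconi anaemia genes, 21 rose and 2 fell, with a median of 0.92 (adjusted p = 0.0013; adjusted p = 0.364 with an estimated correlation). Library totals gave 16 higher and 5 lower (median 0.61), and on log2(TPM + 1) values 14 of 29 rose and 5 fell (median 0.46). CLSPN, an adaptor of the replication checkpoint, rose by 2.59 and FANCA by 1.95, while the checkpoint kinase gene ATM fell by 1.60 on the log2 scale.

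Mitotic genes moved less. Of 30 members, 11 rose, 2 fell and 17 did not pass, and the list did not pass (median 0.24, adjusted p = 0.284). FOXM1, a transcription factor of G2/M genes, rose by 1.90, BIRC5 by 1.79 and CDK1 by 1.27. The kinesin gene KIF20A fell by 0.58 on the log2 scale, and it lost its call without CCT068127 replicate 1 (adjusted p = 0.132) or CCT068127 replicate 3 (adjusted p = 0.098) and stood at -0.34 without DMSO replicate 1. The mean of the list per library, relative to the DMSO mean, was 0.42 in DMSO replicate 1 and -0.18 and -0.23 in DMSO replicates 2 and 3, and 0.19, 0.47 and 0.40 in CCT068127 replicates 1 to 3. Without DMSO replicate 1 the list passed (adjusted p = 0.00752), with a median of 0.48. Without DMSO replicate 2, 7 rose and 3 fell (median 0.09), without CCT068127 replicate 2, 6 rose and 1 fell (median 0.14), and with scaling by library totals 6 rose and 11 fell (median -0.07). The replication list mean was 2.25, 2.19 and 2.18 in CCT068127 replicates 1 to 3. The difference between the replication and mitosis means was -0.16, 0.10 and 0.06 in the DMSO libraries and 2.05, 1.72 and 1.79 in the CCT068127 libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows).

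Immediate early and short-lived transcripts rose in 20 of 25 cases and fell in 3 (median 1.58, camera adjusted p = 2.28e-06; adjusted p = 0.206 with an estimated correlation). FOS rose 18.2-fold, from 27.5 ± 8.99 to 490 ± 34.9 CPM, JUNB 7.99-fold and IER3 5.39-fold, while JUND fell by 0.88 on the log2 scale. Among 15 heat shock chaperone genes 14 rose and 0 fell (median 0.90, adjusted p = 1.72e-05; adjusted p = 0.159 with an estimated correlation). The number that rose was 11 with scaling by library totals (median 0.58) and 8 on log2(TPM + 1) values (median 0.44), with 0 lower in both. HSP90AA1, the inducible HSP90 gene, rose from 575 ± 19 to 2974 ± 437 CPM, BAG3, a co-chaperone gene, by 1.59 and HSPE1, a mitochondrial chaperonin gene, by 1.63.

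The integrated stress and unfolded protein response list went the other way, with 17 of 22 members lower and 4 higher (median -1.43, camera adjusted p = 3.31e-07; adjusted p = 0.169 with an estimated correlation). DDIT4, an inhibitor of mTORC1 signalling, fell from 781 ± 44.1 to 95.1 ± 6.82 CPM. ASNS, asparagine synthetase, fell from 176 ± 25.5 to 18.8 ± 2.13 CPM, and STC2 from 951 ± 36 to 304 ± 6.07 CPM. PDIA4, a disulfide isomerase of the endoplasmic reticulum, rose by 1.39. Of 24 p53 targets 5 rose and 11 fell (median -0.23, or -0.16 without CCT068127 replicate 1), and the number that rose was 3 without DMSO replicate 2, CCT068127 replicate 1 or CCT068127 replicate 3. TP53I3 (-1.81 ± 0.14), CCNG1 (-1.39 ± 0.12) and SESN2 (-1.85 ± 0.17) were lower, and PPM1D rose by 0.59, a call lost with scaling by library totals (0.28, adjusted p = 0.0684) and on log2(TPM + 1) values (0.07, adjusted p = 0.634). With library totals 1 member of the list rose and 15 fell, and on log2(TPM + 1) values 0 rose and 15 fell. The list lay at the threshold (adjusted p = 0.0591), and it passed without DMSO replicate 2 (adjusted p = 0.0339), without DMSO replicate 3 (0.0325), without CCT068127 replicate 3 (0.0377), with fry (0.0063) or without a low-count filter (0.00621). Of 13 BCL2 family genes 3 rose and 5 fell (median -0.13, adjusted p = 0.247), with a median of -0.28 without CCT068127 replicate 1, and the list passed with fry (adjusted p = 0.00143). BMF, a pro-apoptotic member, fell from 99.4 ± 31.3 to 6.86 ± 1.65 CPM, BCL2L2 fell by 1.38 and BBC3, which encodes PUMA, by 1.03 on the log2 scale, and BID rose by 0.67, with no call on log2(TPM + 1) values (0.17, adjusted p = 0.144). Library totals gave 2 members of the list higher and 8 lower.

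Cholesterol biosynthesis genes rose in 23 of 24 cases, with a median of 1.62 (camera adjusted p = 1.83e-09; adjusted p = 0.224 with an estimated correlation). MSMO1, a sterol demethylase, rose 14.1-fold, from 23.8 ± 5.62 to 343 ± 69.2 CPM. SQLE, squalene epoxidase, rose by 1.90. Hypoxia and glycolysis genes rose in 17 of 25 cases and fell in 2 (median 1.07, adjusted p = 1.72e-05; adjusted p = 0.307 with an estimated correlation). The members that rose with the smallest adjusted p were the glycolytic PGK1 (1.94), PGAM1 (1.85) and PKM (1.59), and the angiogenic factor VEGFA fell by 1.43 on the log2 scale. Lysosome and autophagy genes rose in 19 of 26 cases and fell in 6 (median 0.93, adjusted p = 0.000859; adjusted p = 0.204 with an estimated correlation). The lysosomal genes CTSB (1.75) and LAMP1 (1.49) rose, and the autophagy kinase gene ULK1 fell by 1.68 on the log2 scale.

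Nuclear oxidative phosphorylation genes rose in 23 of 34 cases and fell in 3 (median 0.57, adjusted p = 1.74e-06; adjusted p = 0.224 with an estimated correlation). ATP5MC1 (2.22), NDUFA4 (2.13) and COX7A2 (1.89) rose. The list median was 0.26 with scaling by library totals, and 0.07 on log2(TPM + 1) values, where 16 rose and 9 fell. Of 13 mitochondrially encoded genes 7 rose and 0 fell, and that list did not pass (median 0.62, adjusted p = 0.516). Their share of counts was 2.39%, 2.41% and 2.27% in the DMSO libraries and 2.01%, 4.08% and 2.43% in CCT068127 replicates 1 to 3, and without CCT068127 replicate 2 the median was 0.29, with 7 members higher and 3 lower. The number that rose was 3, 2 and 1 without DMSO replicates 1, 2 and 3 in turn, and 4 with the deep libraries thinned. With DMSO replicate 3 as the sole control the list median was 0.68. Scaled by library totals, 1 rose and 2 fell, and on log2(TPM + 1) values 0 rose and 2 fell. COX1 (0.67), COX2 (0.55) and ND4L (0.62) rose, with values of 0.40, 0.29 and 0.30 without CCT068127 replicate 2. Without DMSO replicate 3, COX2 (adjusted p = 0.0526) and ND4L (adjusted p = 0.059) lost their calls. ND4L lost its call also without DMSO replicate 2 (adjusted p = 0.051). With scaling by library totals none of COX1, COX2 and ND4L passed (adjusted p = 0.0736, 0.205 and 0.169), nor did they on log2(TPM + 1) values (adjusted p from 0.496 to 0.878). Ribosome biogenesis genes rose in 15 of 25 cases and fell in 3 (median 0.44, camera adjusted p = 0.12). That list passed with fry as higher (adjusted p = 0.000494). PA2G4 (0.99), NOLC1 (0.91) and NOP16 (0.95) were higher, and POLR1A, a subunit of RNA polymerase I, stood at -0.65. On log2(TPM + 1) values 4 ribosome biogenesis genes rose and 8 fell (median -0.03). Cytosolic ribosomal protein genes split into 13 that rose and 14 that fell (median 0.01, mean -0.01, adjusted p = 0.695). RPLP2 rose by 1.42, while RPL3 (-0.99), RPS6 (-0.85) and RPL23 (-0.84) were lower. Scaled by library totals, 6 ribosomal protein genes rose and 16 fell (median -0.31).

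Genes used to describe the urothelial cell state also moved. Of 20 basal urothelial markers 11 were tested, and 9 rose and 1 fell (median 2.17, or 0.92 on log2(TPM + 1) values; camera adjusted p = 5.52e-05; adjusted p = 0.159 with an estimated correlation). The keratin gene KRT17 rose 4.5-fold, from 60.5 ± 5.59 to 271 ± 41.5 CPM. KRT14 had 7 counts over the DMSO libraries and 54 over the CCT068127 libraries, a ratio of pooled CPM of 617 (exact 95% counting interval 280 to 1610). KRT17 and KRT14 belong to a family of similar genes that can share reads. EGFR fell by 0.48 on the log2 scale, with no call on log2(TPM + 1) values without a filter (-0.41, adjusted p = 0.104). It stood at -0.40 with DMSO replicate 3 as the sole control. The basal keratin genes KRT5 and KRT6A were too low to test, at 0.00689 and 0.0138 CPM in the pooled DMSO libraries, so the list does not speak for them. Of 20 luminal markers 11 were tested, and 3 rose and 6 fell (median -0.36, adjusted p = 0.0592). Only 1 rose without DMSO replicate 2, DMSO replicate 3, CCT068127 replicate 1 or CCT068127 replicate 3, with medians of -0.53, -0.54, -0.55 and -0.37. The luminal transcription factor genes GATA3 (-2.18) and PPARG (-0.89) and the stress factor gene XBP1 (-1.48) were lower. FGFR3, a growth factor receptor, rose from 0.24 ± 0.06 to 4.98 ± 1.03 CPM. The luminal list passed without DMSO replicate 1 (adjusted p = 0.021), without DMSO replicate 2 (0.0378) and without CCT068127 replicate 1 (0.0416). It also passed with the deep libraries thinned (0.0339), with the replicate number as a block (0.0406) and with fry (0.000693). With DMSO replicate 3 as the sole control its median was -0.34.

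TGF-beta and mesenchymal genes rose in 16 of 23 cases and fell in 3 (median 0.55, adjusted p = 6.36e-05; adjusted p = 0.159 with an estimated correlation). TAGLN, an actin-binding protein of contractile cells, rose from 349 ± 62 to 3841 ± 296 CPM, and SNAI1, a repressor of epithelial genes, from 0.90 ± 0.26 to 25 ± 4.27 CPM. ZEB2, another such repressor, fell by 1.13 on the log2 scale. Scaled by library totals, 10 members of the list rose and 3 fell (median 0.23), and 10 rose and 2 fell without DMSO replicate 2. Epithelial junction genes rose in 4 of 16 cases and fell in 10 (median -0.58, adjusted p = 0.12), and the list passed without a low-count filter (adjusted p = 0.0187) and with fry (0.00756). The number that rose was 2 without DMSO replicate 2, DMSO replicate 3, CCT068127 replicate 1 or CCT068127 replicate 3, and also with library totals. CLDN1 (-1.14), ELF3 (-2.73) and DSP (-0.85) were lower, and KRT8 rose by 1.79. RAS-MAPK output genes rose in 6 of 20 cases and fell in 10 (median -0.31, adjusted p = 0.938). SPRY1 (-3.53) and ETV1 (-1.90) were lower, ETV4 fell from 51 ± 4.24 to 25.1 ± 2.9 CPM, and IER3 rose.

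Interferon response genes did not pass with camera (3 of 29 rose, 6 fell, adjusted p = 0.695). With DMSO replicate 3, the DMSO library with the highest mean of the list, as the sole control the median was -0.30. Without DMSO replicate 1, 5 rose and 11 fell (median -0.20), but without DMSO replicate 3, 6 rose and 4 fell (median 0.29). The main-fit median of the list (0.12) and its mean (-0.03) differed in sign, and the median was -0.19 with scaling by library totals. IRF1 (-1.51), OASL (-1.55) and STAT2 (-0.52) were lower and BST2 rose by 1.00, and STAT2 lost its call without CCT068127 replicate 1 (adjusted p = 0.0593) or 3 (adjusted p = 0.0533). The mean of the list per library was -0.69 in DMSO replicate 1 against 0.24 and 0.45 in DMSO replicates 2 and 3. Of 23 NF-kB and cytokine genes 5 rose and 7 fell (median -0.40, adjusted p = 0.618). The mean of that list was -0.47 in DMSO replicate 1 against 0.15 and 0.32 in DMSO replicates 2 and 3. Its lower members numbered 13 without DMSO replicate 1 (median -0.66). With DMSO replicate 3, the DMSO library with the highest mean of that list, as the sole control the median was -0.72. TNFAIP2 (-2.28), RELB (-1.35) and IL1A (-1.09) were lower, and TNFAIP3, a feedback inhibitor of NF-kB, rose by 1.42.

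In a histone list, meant for genes that give polyadenylated transcripts, 11 of 18 genes rose and 3 fell (median 0.97, adjusted p = 0.00289; adjusted p = 0.204 with an estimated correlation). H4C3 rose from 0.17 ± 0.02 to 31.5 ± 3.52 CPM and H2BC8 from 0.66 ± 0.20 to 12.5 ± 1.86 CPM. The variant gene MACROH2A1 rose by 1.15. Of the 18 genes 8, H4C3 and H2BC8 among them, are replication-dependent genes, of which 6 rose and 0 fell (median 1.76). Among the other 10, 5 rose and 3 fell (median 0.33). Reads of H4C3 and H2BC8 can be shared with near-identical histone genes. The share of ribosomal RNA, which has no poly(A) tail, was 0.54%, 0.74% and 0.46% of counts in the DMSO libraries and 1.01%, 1.12% and 1.07% in the CCT068127 libraries.

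Markers of other cell types were examined as well. Of 16 leukocyte markers 7 were tested, and 6 rose and 1 fell (median 2.43, adjusted p = 0.00578; adjusted p = 0.204 with an estimated correlation). CD68 (3.14), LCP1 (2.43) and LYZ (3.88) rose. CD68 is a lysosomal glycoprotein and LCP1 an actin-bundling protein also found in tumour lines. CD14 fell by 0.94 on the log2 scale, and its call held without DMSO replicate 1 or CCT068127 replicate 3 but was lost when any other library was left out (adjusted p from 0.0713 to 0.241), with log2 fold changes of -0.54 without CCT068127 replicate 1 and -1.55 without CCT068127 replicate 3. PTPRC, the pan-leukocyte marker, was below the count filter, at 0.30 CPM in the pooled DMSO libraries and 0.92 CPM in the pooled CCT068127 libraries (ratio 3.07, exact 95% counting interval 1.45 to 5.73). Its counts were 1, 2 and 7 in CCT068127 replicates 1 to 3, and the interval leaves out this spread between libraries. CD3E stood at 0.02 CPM in DMSO, below the 0.28 CPM that 3 counts in the treated libraries amount to, so its 0 counts there decide nothing. Fibroblast markers did not pass with camera (1 of 6 rose, 1 fell, adjusted p = 0.695) but passed with fry as lower (adjusted p = 0.0317; median 0.18, mean -0.16, median -0.12 with scaling by library totals). PDGFRB fell by 2.37 on the log2 scale, and COL6A3 (0.95) lost its call when any library other than DMSO replicate 3 was left out (adjusted p from 0.0543 to 0.152). Endothelial markers did not pass with camera or fry (1 of 5 rose, 2 fell, adjusted p = 0.989; median -0.20, mean 0.28; median 0.06 without DMSO replicate 1 and -0.45 without DMSO replicate 2). TIE1 rose by 2.36, PECAM1 (-1.23) and ENG (-0.46) were lower, and ENG lost its call without CCT068127 replicate 3 (adjusted p = 0.0555).

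**Figure D2:**
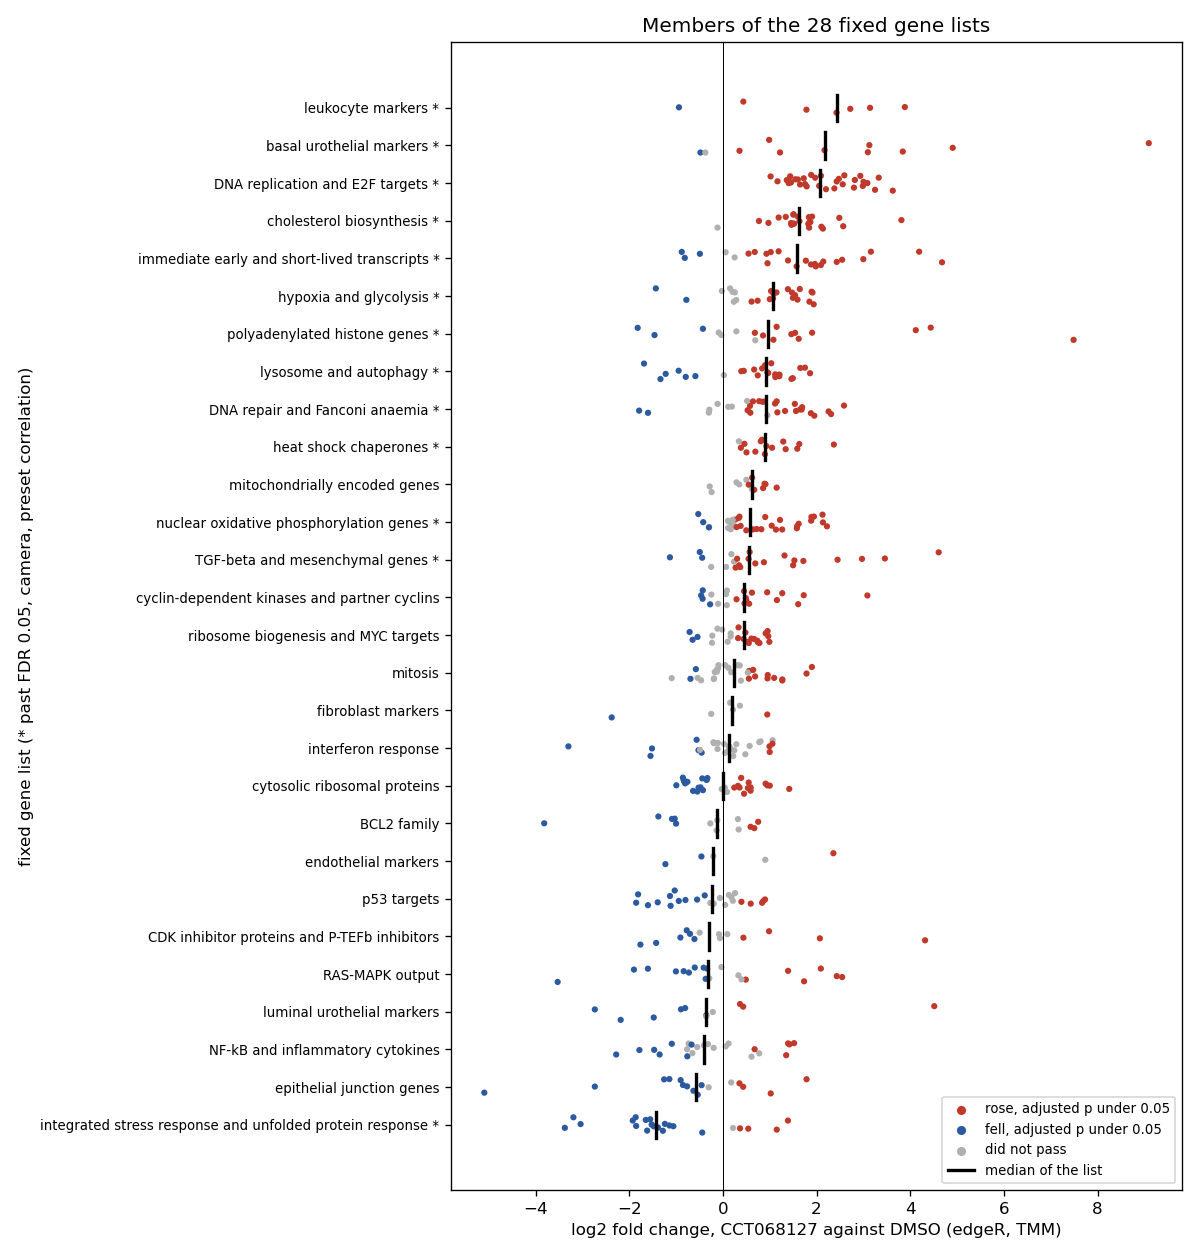
Log2 fold change of CCT068127 against DMSO (x axis, edgeR with TMM) for each tested member of the 28 fixed gene lists (y axis), with 1 point per gene, red for genes that rose, blue for genes that fell, grey for genes that did not pass, and a black bar at the list median. An asterisk marks the lists past the threshold with the preset correlation. The DNA replication list lies wholly above 0 with a median of 2.08, and the stress response list has a median of -1.43, while the medians of mitosis, interferon, ribosomal protein and fibroblast lists turn negative with scaling by library totals.

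In all, 13 of the 28 lists passed with the preset correlation, 0 passed with an estimated correlation, and 20 passed with fry, which tests whether the genes of a list move on balance one way and compares them with no other genes. Counts adjusted over the list alone were the same as over all genes for 18 lists. In the other 10 they were, adjusted over the list alone, 11 higher and 1 lower for mitosis, 5 and 17 for the stress response, 15 and 0 for chaperones, 2 and 3 for interferon, 5 and 6 for NF-kB, 12 and 3 for histones, 15 and 4 for ribosome biogenesis, 23 and 4 for oxidative phosphorylation, 6 and 11 for RAS-MAPK and 0 and 1 for fibroblast markers.

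Scaling also moved other lists. With scaling by library totals and then on log2(TPM + 1) values, the medians were 1.76 and 1.54 for DNA replication, 1.31 and 1.27 for cholesterol synthesis, 1.27 and 0.92 for immediate early genes, -1.74 and -1.86 for the stress response, 0.76 and 0.57 for hypoxia and glycolysis, 0.61 and 0.38 for lysosome and autophagy, -0.60 and -0.74 for CDK inhibitors, -0.71 and -0.84 for NF-kB, -0.62 and -0.73 for RAS-MAPK output, -0.89 and -0.99 for epithelial junctions and -0.67 and -0.78 for luminal markers. The lower members of the CDK inhibitor list numbered 9 and 10, and those of the NF-kB list 10 and 11.

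Calls of other named genes also depended on the analysis. With DMSO replicate 3 as the sole control, log2 fold changes were 0.52 for CCNT1, -0.43 for CDK12, -0.31 for KIF20A, 0.51 for PPM1D and 0.68 for COX1. They were 0.60 for COX2, 0.69 for ND4L, -1.19 for CD14, 0.37 for COL6A3 and -0.44 for ENG. With limma-voom CCNA2 (adjusted p = 0.128), KIF20A (0.127), STAT2 (0.0981), CD14 (0.0881) and PECAM1 (0.0632) lost their calls. Without a low-count filter CCNA2 (0.132), PPM1D (0.154), COX2 (0.065) and COL6A3 (0.246) lost theirs. CCNA2 (0.301) and COL6A3 (0.13) did not pass with scaling by library totals, and CD14 and COL6A3 did not pass with DESeq2 (0.0537 and 0.117) or with the deep libraries thinned (0.0821 and 0.159). COL6A3 did not pass with the replicate number as a block either (0.0811).

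The largest increases among genes with at least 5 CPM were in genes nearly silent in DMSO. KRTAP2-2, a keratin-associated protein gene, had 0 counts in DMSO and 155 in CCT068127. The gene was 4130-fold higher against a floor of 3 counts over the DMSO group, and the exact 95% lower limit from counting error was 3320-fold. Its near-identical copies KRTAP2-1 (0.00115 CPM in pooled DMSO, 2.85 CPM in pooled CCT068127) and KRTAP2-3 (1.6 and 210 CPM) can share its reads. CDHR4 (chromosome 3), a cadherin-related gene, rose from 0.03 ± 0.03 to 89.9 ± 13.9 CPM. ARC (chromosome 8), a neuronal immediate early gene, rose from 0.80 ± 0.09 to 1194 ± 253 CPM, a log2 fold change of 10.61 ± 0.22 (edgeR adjusted p = 1.3e-09). The uncharacterised LOC101928093 and LOC107987293, the zinc finger genes ZNF385D and ZNF667 and the sorting nexin gene SNX32 had log2 fold changes of 9.85, 9.32, 9.06, 8.74 and 8.94.

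The largest decreases left few counts in the treated libraries. VCAM1, a leukocyte adhesion molecule, had 14795 counts over the DMSO libraries and 1 over the CCT068127 libraries, in replicate 2, a ratio of pooled CPM of 185 (exact 95% counting interval 33.2 to 7300). SLC47A2, an organic cation exporter, fell from 68.1 ± 9.9 to 0.37 ± 0.36 CPM. SLC6A9, a glycine transporter, fell from 44.8 ± 1.1 to 0.82 ± 0.52 CPM, and ABCG1, a cholesterol efflux transporter, from 56.3 ± 7.02 to 1.5 ± 0.48 CPM. The antisense gene SSTR5-AS1, the netrin receptor gene UNC5B, the epithelial transcription factor gene EHF and the disulfide isomerase gene AGR2 had log2 fold changes of -6.29, -5.51, -5.31 and -4.99, on 4 to 6 treated counts each. The reads of SSTR5-AS1 could not be separated from those of SSTR5.

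Because CDK9 acts in transcription elongation, fold changes were compared with gene length across 12957 genes, which are not independent replicates. The Spearman correlation with genomic length was -0.0996. Measured in each CCT068127 library against the DMSO mean it was -0.149, -0.0129 and -0.101, against -0.0242 to 0.0179 for each DMSO library compared with the other DMSO libraries. Without CCT068127 replicate 1 it was -0.0664. By length class, of 919 genes over 200 kb, 198 rose and 407 fell (median -0.29), and of 1172 genes under 5 kb, 443 rose and 369 fell (median 0.06).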

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

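The thinned libraries, DMSO replicate 3 as the sole control and scaling by library totals were chosen after seeing the data. With the replicate number as a block, 8297 genes passed (4107 higher, 4190 lower). Same-numbered libraries of the groups had deviation correlations of 0.0347, -0.00297 and 0.0367, and differently numbered ones from -0.0386 to 0.00751. These values show no clear pairing, but counting noise in the shallow libraries could hide a shared batch. Leaving out 1 library gave 7816 to 9242 genes, 3987 to 4452 at 2-fold, 13 to 15 lists and a length correlation from -0.126 to -0.0664. The thinned libraries gave 8366 genes, of which 8203 were called the same way with full depth. Among 127 named genes, 0 changed sign as a call in these alternatives, and leaving out a library ended the call of 9.

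Counts at 2-fold rose without a low-count filter to 7357 (4102 higher, 3255 lower) and with DESeq2 to 6207 (4180 higher). More genes were tested there. DMSO replicate 3 as the sole control left 2740 lower calls on fewer libraries. Scaling by library totals gave 2975 lower at 2-fold. On log2(TPM + 1), calls were 2474 higher and 7472 lower (1216 and 3221 at 2-fold), and without a filter 7365 lower (1312 and 3183 at 2-fold). On log2(TPM + 0.1) they were 2444 higher and 7299 lower (3853 lower at 2-fold). No TMM scaling was applied to the TPM values, so, as with library totals, their zero line was not moved to the bulk of the genes. How much of the TPM difference this made was not tested. With an estimated correlation 0 lists passed, and with fry 20.

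For lists that had not passed, the direction of the list test reversed in some alternatives. The values given here are the list median minus that of all genes, which kept its sign in most of them (at first -0.15 for endothelial markers, -0.26 for RAS-MAPK output, 0.17 for interferon, 0.24 for fibroblast markers and -0.24 for CDK inhibitors). For endothelial markers these were -0.15 with DESeq2 size factors, -0.19 with the replicate block, -0.46 with DMSO replicate 3 alone and -0.41 to 0.11 when leaving out a library. For RAS-MAPK output they were -0.26 with the block, with DMSO replicate 3 alone and with fry, -0.28 when thinned, and -0.31 to -0.19 when leaving out a library. Interferon ranged from -0.16 to 0.35 when leaving out a library, fibroblast markers gave 0.42 without a filter, and CDK inhibitors -0.24 with fry. Values with fry are those of the main fit, since fry changes only the test. The list tests average gene statistics rather than take this median. In the order first given, the mean log2 fold changes of these lists were 0.28, -0.01, -0.03, -0.16 and 0.08. Each was near 0 or opposite in sign to the median of its list. Why each direction turned was not tested. Depth limits the low genes most, with 1966742 counts in CCT068127 replicate 2.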

Other observations

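The lists of this paragraph were chosen after the genes with the largest changes had been seen, and the single genes after their values were seen. The p-values of these lists do not allow for that choice, unlike those of the lists fixed in advance. The bootstrap intervals below, the correlations per library and the use of DMSO replicate 3 as the sole control were also added after seeing the data. Proteasome subunit genes rose in 24 of 31 cases and fell in 0 (median 0.58, camera adjusted p = 7.44e-05; adjusted p = 0.13 with an estimated correlation). With scaling by library totals 16 rose and 4 fell (median 0.27), and on log2(TPM + 1) values 11 rose and 7 fell (median 0.07). PSMD11 rose by 0.38 and PSMA3 by 0.52, and PSMB5 stood at 103 ± 5.57 CPM in DMSO and 102 ± 20.1 CPM in CCT068127. Cytosolic aminoacyl-tRNA synthetase genes, which load amino acids on tRNA and include known ATF4 targets, fell in 12 of 19 cases and rose in 3 (median -0.71, adjusted p = 7.44e-05; adjusted p = 0.131 with an estimated correlation). With scaling by library totals 1 rose and 15 fell (median -1.02). GARS1 (-1.61), WARS1 (-1.57) and MARS1 (-1.50) were lower. NRF2 targets rose in 15 of 22 cases and fell in 5 (median 0.63, adjusted p = 0.00167; adjusted p = 0.13 with an estimated correlation), in 12 and 6 with scaling by library totals (median 0.31) and in 10 and 6 on log2(TPM + 1) values (median 0.12). HMOX1, heme oxygenase, rose from 10.9 ± 0.56 to 384 ± 78.7 CPM and GCLM by 1.61, while SLC7A11, the cystine transporter gene and also a stress response gene, fell by 1.24 on the log2 scale. Of 10 metallothionein genes 5 were tested, and 3 rose and 1 fell (median 0.81, adjusted p = 0.0856; adjusted p = 0.264 with an estimated correlation), with MT2A at 244 ± 54.6 CPM in DMSO and 1800 ± 345 CPM in CCT068127.

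RN7SK, the 7SK RNA, which has no poly(A) tail and scaffolds inactive P-TEFb, had 0.99, 1.39 and 0.89 CPM in DMSO and 42.6, 48.9 and 43.8 CPM in CCT068127, and 15 of 19 replication-dependent histone genes rose and 0 fell (median 2.5; 13 of 16 with genes of identical values counted once). If poly(A) selection had been less complete in the treated libraries, other RNAs without a tail would be higher too, and of 12 tested 8 rose and 4 did not pass, with RN7SL2 at -0.50 (camera adjusted p = 0.00059; adjusted p = 0.131 with an estimated correlation). Their median was 1.35, past the bound of 1 set beforehand, but its bootstrap 95% interval over genes, 0.55 to 3.53, reached below it, and other settings, with other numbers of genes tested, gave from 1.03 over 12 with scaling by library totals, and 1.42 over 31 on log2(TPM + 1) values, to 3.46 over 18 with DMSO replicate 3 as the sole control. Among the 12 are several copies of 45S pre-rRNA, 28S rRNA and 7SL RNA, so the count and the interval treat related entries as separate. Summed over copies, 45S pre-rRNA was 14.7-fold, 18S rRNA 3.25-fold and 28S rRNA 1.7-fold as high, and 7SL RNA 0.861-fold. Weaker selection may account for part of the increase and stays open beside a treatment effect, which was not tested.

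The length trend may reflect transcript length more than gene length. Given mature transcript length, the Spearman correlation of fold change with genomic length was -0.0298 (bootstrap 95% interval over genes -0.048 to -0.0115). This lay above the bound of -0.05 set beforehand. In CCT068127 replicates 1 to 3 it was -0.0682, 0.0315 and -0.0326, so replicate 1 lay below the bound. Mature length itself gave -0.162 (by library -0.198, -0.0906 and -0.159). A difference in RNA integrity or fragment selection between the groups is therefore a candidate explanation. GC content and the depth of DMSO replicates 1 and 2 each needed a corrected correlation above -0.05, and it was -0.109 given GC content (-0.126 to -0.0916; by library -0.111, -0.0838 and -0.119), -0.0975 with DMSO replicate 3 as the sole control (-0.115 to -0.0819) and -0.101 with the deep libraries thinned (-0.121 to -0.0829), while GC content itself had a correlation of -0.00403 with fold change (-0.0212 to 0.0134). These values argue against GC content and against depth as the whole cause, by a reading chosen after they were seen, and the stricter bound of -0.1 set beforehand, as large as the uncorrected -0.0996, was not passed by the whole of the GC interval or the depth intervals. Before the GC correction the correlations by library were -0.149, -0.0129 and -0.101. The correction thus weakened the trend in CCT068127 replicate 1 and strengthened it in replicates 2 and 3. The correlation of GC content with fold change over the libraries together does not show this. A treatment effect stays open and was not tested, and the intervals cover genes, while with DMSO replicate 3 as the sole control the correlations by library were -0.142, -0.00938 and -0.0955.

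Genes under 5 CPM in DMSO could rise through transcription running past the end of an expressed neighbour. With such a neighbour within 10 kb, 69 of 173 genes on the same strand and 54 of 147 in divergent position rose at least 2-fold, an odds ratio of 1.14 (95% interval 0.727 to 1.8, two-sided Fisher's exact p = 0.64), and the interval is too wide to tell. Of genes with no such neighbour, a class compared after the result was seen, 532 of 1206 rose, and the odds ratio of same-strand genes against them was 0.841 (0.607 to 1.16). Of the 655 genes that rose, these 532 had no such neighbour within 10 kb. All these classes hold only genes past the low-count filter. A gene under 1.74 CPM in every DMSO library passed it only where all 3 treated libraries reached that level. The shares that rose were therefore partly set by the filter and are no rates for all genes low in DMSO. Neighbours further away or downstream, and genes that overlap an expressed gene, were not examined. The comparison therefore cannot decide how much of the rise came by this route.

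The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 8793 genes, and 1 of 10 splits gave as many, with 0 the highest of the others. At 2-fold it gave 3868, and 1 of 10 gave as many, with 0 the highest of the others. For lists, 6 of the 10 splits gave at least the 13 of the real one, and the highest other gave 16. Every other split mixed libraries of both treatments, with more DMSO libraries in 1 part than in the other. It therefore kept some of the treatment difference between its parts and put the rest inside them. Such splits are no reference free of treatment, so their counts of genes and lists decide nothing here.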
